A study of Mus musculus with 7 samples.

How the data were processed

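The deposited table holds 7 arrays, 1 per lens, from 3 KO and 3 WT mice of 1 litter, per the labels. Per the labels' protocols, lenses were cryosectioned and stained, epithelial cells were removed by laser capture, RNA was extracted with a column kit, and it was amplified in a pair of cycles and labelled with biotin. The deposited values are linear intensity values, one summary signal per probe set of an Affymetrix mouse array. Tested on the table, each array had the same mean signal after trimming 2% at each end, so the arrays share a scale but not a distribution. The summary software, its background correction and its version are not given in the sources used here. Scanner-level files were not used here, so signal over background could be gauged only from the bacterial control probe sets.

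From these values, 64 control probe sets were left out and 45037 of 45101 were kept with no filter on low values. The values were turned into log2(signal + 16) and quantile normalized between arrays. Because of the pseudocount, a log2 difference understates the change of a weak probe set. Where every WT lens of a gene lay at or under the highest bacterial control and every KO lens above it, the gene is given as at least so many fold higher, the KO mean against WT lenses set to that control's signal on the normalized scale of each array, a rule added after the data had been seen. The lenses 1L and 1R of KO animal 1 were averaged on the log2 scale. Two-round amplification starts at the 3' end of transcripts and favours probe sets near it, and probe sets far from it can be low for that reason.

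Gene names came from the platform annotation, where 34945 probe sets had 1 symbol, 932 several and 9160 none. Of those with 1 symbol, 34741 were found by gene number in the reference gene table of assembly GRCm38.p6, 0 symbols were updated, and 204 kept the platform's symbol. The files name no genome build, so the reference served only for names and for the order of genes around Sparc, and no coordinates are given. Probe sets with several symbols were not named.

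KO and WT animals were compared with limma 3.58.1 (lmFit and eBayes with an intensity trend) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all probe sets and a threshold of 0.05. Animals came from 1 litter and are separate mice. Gene lists were tested with camera from limma, with a preset inter-gene correlation of 0.01, on the probe set with the highest mean for each gene, and adjusted over 29 lists. Of 30 lists written for the study, the remaining one held sex-linked genes and served only to check labels. The lists covered the lens, extracellular matrix, signalling, stress and metabolism, and the neighbouring tissue that laser capture could have taken along. Neighbouring genes of Sparc were tested with Fisher's exact test, and array quality with exact permutation tests.

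Genes were named by a fixed rule. It took Sparc, then up to 12 genes higher and 12 lower in KO with 1 symbol, no overlap between KO and WT lenses and a level above the median of all probe sets in at least 1 group. Too few passed the threshold, so the places were filled by smallest unadjusted p with an absolute log2 difference of at least 1, as measured. It also took up to 3 members of each list with the smallest p, of which the text gives those it describes, and other members are named where they show the level of a list. The grouping, the lists, this rule, the tests and most alternative settings were set before the data were examined. A list of 30 acute-phase genes was added later, after the leading probe sets had been seen.

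The code was tested on simulated data with the means and spreads of the real probe sets, with 200 changed probe sets above the median level in each of 20 runs and no correlation between genes. For KO against WT it recovered 4.6% of 2-fold, 51.1% of 4-fold, 82.8% of 8-fold and 94.1% of 16-fold changes, with 3.1 false calls per run. Benjamini-Hochberg adjustment is stricter where fewer probe sets differ, and 3 passed in the real data. The shares recovered with 200 changed probe sets therefore overstate what could be found if few probe sets differ. Of gene lists shifted by 0.5 on the log2 scale, 95% were found, with 0.05 false lists per run. The correlation estimated in the real lists reached 0.584 (photoreceptors), unlike in the simulation. Wrong splits of the 6 animals into 3 and 3 gave 1 to 6 lists past the threshold. The simulated rate of false lists therefore does not carry over to these data.

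The alternative settings were the 7 lenses as independent samples, either lens of KO animal 1 alone, median centring, a filter on low values, no intensity trend, array weights, pseudocounts of 1 and 64, an adjusted p of 0.1, an estimated correlation or the mean of all probe sets in camera, other windows and thresholds around Sparc, and leaving out each animal in turn. The signals as deposited, and a block for the animal with a correlation set by hand to 0.5, were added after the data had been seen.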

Results

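Expression was measured in the lens epithelium of 28-day-old SPARC-null (KO) mice and wild-type (WT) littermates, to learn which transcripts differ when SPARC is missing. SPARC (secreted protein acidic and rich in cysteine) is a matricellular glycoprotein that binds collagen IV, a main component of the lens capsule on which the epithelium sits. Epithelial cells were cut from stained cryosections by laser capture, a microscope-guided dissection, and the RNA of each lens was amplified in 2 rounds and hybridised to its own Affymetrix mouse array. 4 KO lenses came from 3 animals (both eyes of animal 1, left eyes of animals 4 and 7) and 3 WT lenses from 3 animals (left eyes of animals 2, 5 and 6). Lenses are named by animal and eye (1L, 1R, 4L, 7L, 2L, 5L, 6L). The animal was the unit of replication, so the values of 1L and 1R were averaged and n = 3 in each group. KO animal 7 was labelled male and the other 5 animals female. Each array had a trimmed mean signal of 500.003 or 500.004, and the number of arrays limits the precision of every value.

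The signal of Gapdh at its 3' end over that at its 5' end, a measure of RNA integrity, is lower where RNA is more intact. It was 3.75 in the WT lens 2L and 9.06 to 15.9 in the other 6 lenses. The beta-actin ratio was 5.89 in 2L and 13.8 to 23.8 in the others. By these ratios alone 2L had the most intact RNA. Its array also had the lowest signals of the added controls BioB (848, others 1321 to 1907) and CreX (20809.6, others 32835.5 to 44107.7). These controls do not come from the RNA of the lens. Low signal of the array itself can therefore not be told apart from RNA integrity in these ratios. The Gapdh ratio averaged 11.6 ± 2.38 in KO and 9.57 ± 6.09 in WT animals (SD, n = 3; exact permutation test, two-sided, p = 0.7, where 0.1 is the smallest p that 3 animals against 3 can give).

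The labels were checked first with Sparc itself. Sparc transcript fell by 9.94 on the log2 scale (SE 0.34) at the brightest of its 3 probe sets, from 15.38 ± 0.02 in WT to 5.44 ± 0.76 in KO animals (SD, n = 3). The limma adjusted p was 3.41e-06, and all 4 KO lenses lay below all 3 WT lenses. The next brightest probe set fell by 9.37 (SE 0.38, limma adjusted p = 1.10e-05), in 4 of 4 KO lenses. The deposited signals of the brightest probe set were 8.14 to 70.5 in the KO lenses and 27371 to 49972 in the WT lenses. Those of the next were 5.36 to 52.0 and 22968 to 27204. As a gauge of background, 27 bacterial control probe sets with no target in mouse RNA gave signals of 0.199 to 45.5. At the brightest probe set 2 of the 4 KO lenses lay at or under that highest control, and WT lenses lay near the top of their arrays (27371 of a highest signal of 28328 in 2L), so the size of the fall is not resolved beyond these limits. The remaining Sparc probe set was low in both groups, at 85.0 to 129 in KO and 9.25 to 118 in WT lenses (log2 difference 0.86, SE 0.57, limma adjusted p = 0.99988). The deleted part of the gene is not given in the sources used here, so the position of these probe sets relative to it was not set.

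**Figure D1:**
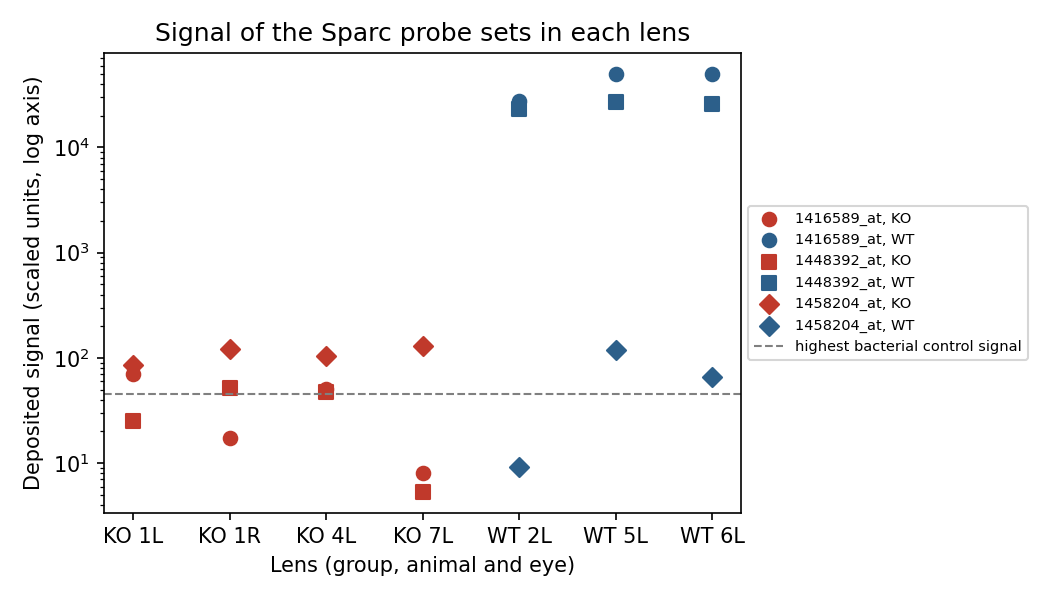
Deposited signal (log axis, scaled units) of 3 Sparc probe sets in each of the 7 lenses, KO in red and WT in blue, with a dashed line at the highest bacterial control signal. At the brightest probe set the KO lenses sit at 8.14 to 70.5 and the WT lenses at 27371 to 49972, while the dimmest is low in both groups, at 9.25 to 129.

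Beyond Sparc, 1 probe set passed the test. This probe set, which the annotation pairs with several genes and which is therefore not named, rose by 3.14 on the log2 scale (SE 0.30), an 8.82-fold difference, from 9.08 ± 0.42 in WT to 12.22 ± 0.48 in KO animals (SD, n = 3). It was higher in 4 of 4 KO lenses than in any WT lens, with a limma adjusted p of 0.0186. It is singled out here after its values were seen. In total 3 of 45037 probe sets passed an adjusted p of 0.05 in limma, 1 higher and 2 lower in KO. At an unadjusted p under 0.05 there were 1828 (4.06%), where 5% would be 2252 with no effect, 1011 of them higher and 817 lower. That split moved to 801 higher and 1092 lower with median centring, and to 1271 and 574 with the signals as deposited. KO and WT lenses did not overlap at 2399 probe sets (5.33%), where chance gives 5.71% for 4 against 3. That chance value treats the lenses as exchangeable, although 1L and 1R come from 1 animal. The call of the unnamed probe set was lost without the intensity trend (adjusted p = 0.225) and without KO animal 1 (0.108), KO animal 4 (0.0879), KO animal 7 (0.118), WT animal 5 (0.184) or WT animal 6 (0.179), and was kept without WT animal 2 (0.0339), while its log2 difference stayed at 2.86 to 3.40 under all alternatives.

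Among genes with higher values in KO, none of which passed the adjustment in limma, Socs3, a feedback inhibitor of cytokine signalling through STAT3, was at 11.51 ± 0.44 in KO and 8.63 ± 0.83 in WT animals (log2 difference 2.88, SE 0.40, unadjusted p = 3.14e-05). Its other probe sets differed by 2.31 and 1.64. Tacr3, the neurokinin B receptor, had the smallest p of all named genes apart from Sparc (log2 difference 2.12, SE 0.28, unadjusted p = 2.03e-05). Serping1, the C1 inhibitor of the complement cascade, was at 13.43 ± 0.32 in KO and 11.93 ± 0.45 in WT. The difference was 1.30 (SE 0.25) for Tnfrsf1a, a receptor of tumour necrosis factor. For Bcl3, an atypical IkB protein, and Kng1, the kininogen precursor, all 3 WT lenses lay at or under the highest bacterial control. Against that level Bcl3 was at least 2.73-fold and Kng1 at least 2.97-fold higher in KO, and the other Kng1 probe set differed by 0.42. Piezo2, a mechanically gated ion channel, differed by 2.23, Pcdh9, a protocadherin, by 1.70, and Neurod4, a neural transcription factor, by 1.61. Lin7a differed by 1.55, Tgm2, a transglutaminase, by 1.27, and Glycam1 by 1.14. For Glycam1 the lenses of KO animal 1 lay at 11.64 (1L) and 10.20 (1R), further apart than the KO and WT means. The limma adjusted p of these 12 genes ran from 0.229 to 0.918. Each was higher in 4 of 4 KO lenses than in any WT lens, which the naming rule required and which adds no support. One Tgm2 probe set differed by -0.21 and one of Pcdh9 by -0.25, but both were weak in KO (4.19 and 4.85) and in WT (4.40 and 5.11). Their direction is therefore not resolved. The other Tgm2 probe sets differed by 0.21 to 0.87 and the other one of Pcdh9 by 0.99.

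Among the 12 genes named as lower in KO, again none past the adjustment, Upk1b, a uroplakin of surface epithelia, had the smallest p (limma, unadjusted p = 6.32e-04). It was at 8.56 ± 0.21 in KO and 9.93 ± 0.44 in WT (log2 difference -1.37, SE 0.28). Fmod, the collagen-binding proteoglycan fibromodulin, was at 10.06 in KO and 11.20 in WT animals (log2 difference -1.14, SE 0.26), and its other 5 probe sets differed by -0.84 to -0.46. Galnt10, which starts mucin-type glycans, differed by -2.09 at 1 probe set and by 0.46 and 0.11 at the others. Those others were brighter (10.91 in KO and 10.45 in WT, and 9.00 and 8.89), so the lower value rests on the weakest Galnt10 probe set. The difference was -1.77 (SE 0.47) for Nnat, -1.66 for Tmem45a, -1.60 for 2610507I01Rik, -1.44 for Kcne1, a potassium channel subunit, and -1.37 for Smn1. For Smn1 the lenses of KO animal 1 lay at 6.36 (1L) and 4.23 (1R), further apart than the KO and WT means. Slc1a1, a glutamate and cysteine transporter, differed by -1.37, Dcp1b, a decapping factor, by -1.30, Zfp39 by -1.23 and 4933439C10Rik by -1.21. At Galnt10, Tmem45a, 2610507I01Rik and Smn1, 3 of the 4 KO lenses lay at or under the highest bacterial control, so the sizes of these differences are not well resolved. Other probe sets lay the other way for Slc1a1 (0.13, SE 0.23), Dcp1b (0.60, SE 0.42) and Zfp39 (0.05, SE 0.38). Those of Slc1a1 (4.56 in KO, 4.44 in WT) and Zfp39 (5.34 and 5.28) were weak in both groups, so their direction is not resolved. The remaining probe set differed by -0.22 for Slc1a1 and by -0.65 for Dcp1b. The limma adjusted p of these 12 genes was 0.918 for Upk1b and 0.99988 for the others. Each was lower in 4 of 4 KO lenses than in any WT lens, again because the naming rule required it.

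**Figure D2:**
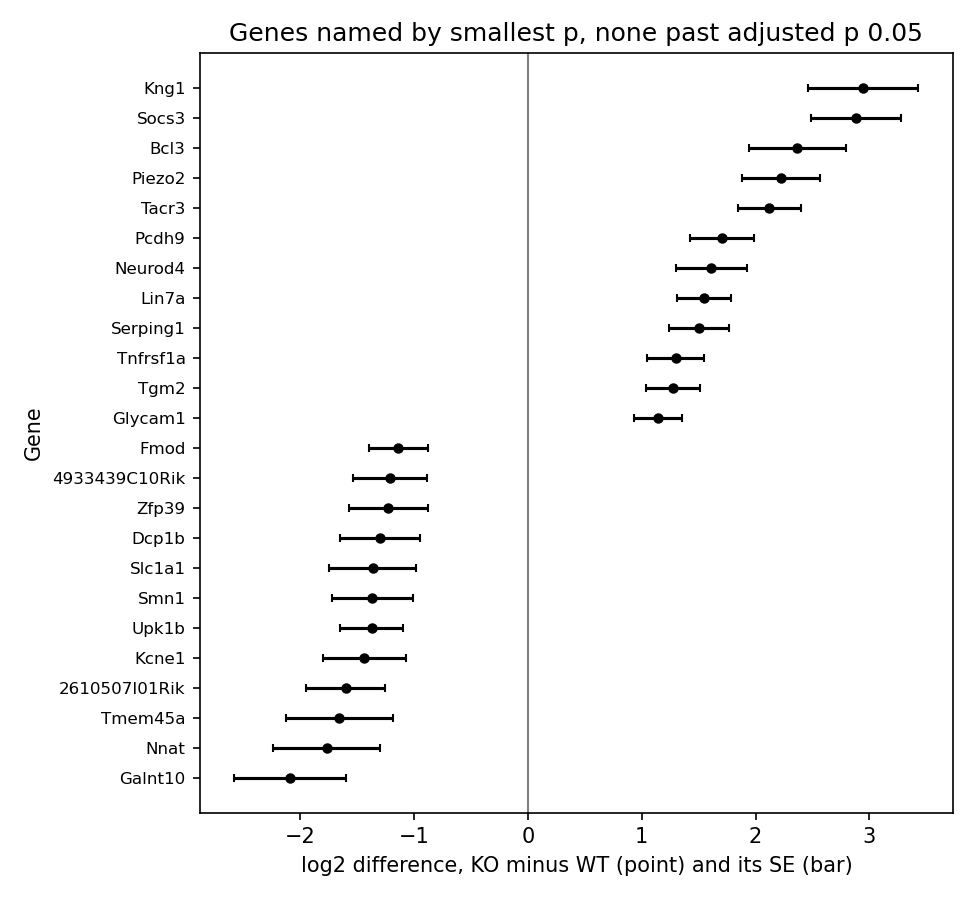
log2 difference between KO and WT animals (points, with bars for the SE from limma, n = 3 in each group) of 12 genes higher and 12 genes lower in KO. They have the smallest p among genes with no overlap between KO and WT lenses, a level above the median and an absolute log2 difference of at least 1. None passed an adjusted p of 0.05, and the points of Kng1 and Bcl3 rest on WT lenses at or under the highest bacterial control, so the sizes plotted for them are not resolved.

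No list of lens genes passed the test. Of 14 measured crystallins, the structural proteins of the lens, 11 had higher and 3 lower values in KO, with a median log2 difference of 0.06 (camera adjusted p = 0.448). Cryba1 was at 15.14 ± 0.08 in KO and 14.99 ± 0.14 in WT animals (SD, n = 3). Crystallin probe sets lay near the top of the arrays (median level 15.06 in KO and 14.94 in WT), as Sparc did in WT, so differences among them are not well resolved. Of 22 lens epithelium genes, 15 were lower (median -0.10, camera adjusted p = 0.198), among them Foxe3, a transcription factor of this epithelium, at 5.44 ± 0.58 in KO and 6.47 ± 0.65 in WT, with 3 of 4 KO lenses at or under the highest bacterial control. Of 21 lens fibre differentiation genes, 16 were lower (median -0.17, camera adjusted p = 0.0683). Dnase2b, the nuclease that degrades fibre cell DNA, was at 11.51 ± 0.09 in KO and 12.34 in WT animals (log2 difference -0.83, SE 0.17). It passed adjusted over the list alone but not over all probe sets (limma adjusted p = 0.918). That SD hides a spread within KO animal 1, whose lenses lay at 10.43 (1L) and 12.49 (1R), the second above all WT lenses. The Dnase2b log2 difference was -1.18 with the left lens of that animal only and -0.49 with the right. No member of the crystallin or lens epithelium lists passed either adjustment in limma, and 0 had an unadjusted p under 0.05. Without WT animal 2 the median was -0.06 for the fibre list (camera adjusted p = 0.473) and -0.03 for the epithelium list (0.955). The fibre median was also nearer 0 without KO animal 7 (-0.10), with the right lens of KO animal 1 only (-0.07) and with array weights (-0.05), and the epithelium median was -0.05 without KO animal 4 and -0.19 with median centring. In camera the fibre list passed without WT animal 6 (adjusted p = 0.0180, median -0.25) and with the left lens of KO animal 1 only (0.00778), and the epithelium list without WT animal 5 (0.0387, median -0.17).

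No list of matrix genes passed the test. For the basement membrane list, which holds the capsule collagens and laminins, 17 of 24 genes were lower (median -0.11, camera adjusted p = 0.340). Col4a1 was at 15.32 in KO and 15.23 in WT, Col4a2 at 15.16 and 15.17, both near the top of the arrays, and Lamb3, a laminin chain, at 5.47 and 6.43 (log2 difference -0.97, SE 0.35), with 3 of 4 KO lenses of Lamb3 at or under the highest bacterial control. For the other members of the SPARC family and matricellular proteins, 13 of 22 were lower (median -0.12, camera adjusted p = 0.999). Sparcl1, the closest relative of SPARC, was at 9.21 ± 0.55 in KO and 8.49 ± 0.57 in WT, and Thbs4, a thrombospondin, at 7.77 ± 1.16 and 9.03 ± 0.96 (SD, n = 3). Fibrillar collagen and stromal genes had a median of -0.16 (camera adjusted p = 0.762) and integrin and focal adhesion genes one of 0.03 with a mean of -0.03 (0.999), the median being -0.038 with median centring. TGF-beta and epithelial-mesenchymal transition genes had a median of 0.06, or -0.0045 with median centring (camera adjusted p = 0.340). Timp1, an inhibitor of matrix metalloproteinases, was at 10.70 ± 0.81 in KO and 9.29 ± 0.24 in WT (log2 difference 1.41, SE 0.37). No member of these 5 lists passed over all probe sets or over the list alone in limma, and 5 of their genes had an unadjusted p under 0.05.

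Of 28 antioxidant and glutathione genes, 20 were lower in KO, with a median log2 difference of -0.21 (camera adjusted p = 0.0227; adjusted p = 0.618 with an estimated correlation). The mean over the list was lower in 4 of 4 KO lenses than in any WT lens, a separation that chance gives in 5.71% of cases for 4 lenses against 3. The list passed on these same lenses, and 1L and 1R are of 1 animal, so this adds little. Gsta4, a glutathione transferase, was at 11.70 ± 0.12 in KO and 12.22 ± 0.02 in WT, Gstm1, another transferase, at 13.71 ± 0.15 and 14.20 ± 0.17, and Msra, which repairs oxidised methionine, at 9.36 ± 0.21 and 9.85 ± 0.15 (SD, n = 3). For Gstm1 the SD hides a spread within KO animal 1, whose lenses lay at 14.27 (1L) and 13.02 (1R). Its lens 1L lay above the WT lenses 2L (14.03) and 6L (14.20). No member passed over all probe sets or over the list alone in limma, and 2 had an unadjusted p under 0.05. In camera the list lost its call without KO animal 1 (adjusted p = 0.0518), WT animal 2 (0.0989, median -0.12), KO animal 4 (0.0691) or KO animal 7 (0.0773), without the intensity trend (0.0632), and with the mean of all probe sets of a gene (0.0582).

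Of 7 lists of markers of other cell types that the dissection could have taken along, 3 passed in camera with the preset correlation and 0 with an estimated one. Of 21 macrophage and leukocyte genes, 16 were higher in KO, with a median of 0.46 (camera adjusted p = 0.00350; adjusted p = 0.772 with an estimated correlation). The mean over the list was higher in 4 of 4 KO lenses than in any WT lens. Chance separates 4 lenses from 3 in 5.71% of cases. The list passed on these same lenses, and 1L and 1R are of 1 animal, so this adds little. C1qa, a subunit of complement C1q made by macrophages, was at 7.54 ± 0.45 in KO and 5.93 ± 0.74 in WT, where 2 of 3 lenses lay at or under the highest bacterial control, and Csf1r, the receptor of macrophage growth factor, at 10.16 ± 0.34 and 9.11 ± 0.66 (SD, n = 3). Aif1, another macrophage marker, was at or under the highest bacterial control in all 7 lenses. The mean over this list was 0.53 above the average of the animals in KO lens 4L and -0.02 to 0.05 in the other 3 KO lenses, and without KO animal 4 the list lost its call (median 0.24, camera adjusted p = 0.172). The median was 0.84 with the filter on low values, 0.26 with a pseudocount of 64 and 0.21 with array weights. No member passed over all probe sets or over the list alone in limma, and 5 had an unadjusted p under 0.05, 4 higher in KO and 1, Aif1, lower.

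Of 14 blood and endothelial genes, 12 were higher (median 0.19, camera adjusted p = 0.0227, or 0.618 with an estimated correlation). Their mean was higher in 4 of 4 KO lenses than in any WT lens, which chance gives in 5.71% of cases. As above, the list passed on these same lenses and 1L and 1R are of 1 animal, so this adds little. Alas2, the haem synthesis enzyme of red cells, was at 6.31 ± 0.48 in KO and Slc4a1, the red cell anion exchanger, at 6.48 ± 1.34 (SD, n = 3). All 3 WT lenses of both lay at or under the highest bacterial control, as did 1 of the 4 KO lenses for Alas2 and 2 for Slc4a1, so no fold is given. Alas2 passed adjusted over the list alone and not over all probe sets. In camera this call was lost without WT animal 6 (adjusted p = 0.129), without KO animal 7 (0.294, median 0.07), with the filter on low values (0.142) and with array weights (0.0753, median 0.06). The median was 0.38 without KO animal 4, 0.31 without KO animal 1 and 0.12 with a pseudocount of 64.

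Of 15 corneal and surface epithelium genes, 10 were lower (median -0.60, camera adjusted p = 0.0229; adjusted p = 0.772 with an estimated correlation), and their mean was lower in 2 of 4 KO lenses, 4L and 7L, than in any WT lens. Krt5 was at 8.90 ± 1.87 in KO and 10.56 ± 0.41 in WT, and Krt13 at 7.12 ± 0.94 and 8.05 ± 0.32 (SD, n = 3); both are keratins of stratified epithelia. Upk1b passed adjusted over this list alone. In camera the call was lost with 7 lenses as independent samples (adjusted p = 0.227), the right lens of KO animal 1 only (0.0851), the filter on low values (0.0743, median -0.39) and array weights (0.325, median -0.25). It was also lost without WT animal 2 (0.130, median -0.40), KO animal 4 (0.189) or KO animal 7 (0.206, median -0.21), and the median was -0.98 without KO animal 1 and -0.37 with a pseudocount of 64.

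The remaining marker lists did not pass in camera. The median was -0.16 for photoreceptors and retina (camera adjusted p = 0.146), 0.42 for pigmented epithelium and melanocytes (0.234), 0.21 for the non-pigmented ciliary epithelium (0.201) and 0.02 for muscle (0.708), the last being -0.031 with median centring and -0.0084 with a pseudocount of 64. In camera photoreceptors passed without WT animal 6 (adjusted p = 1.05e-09, median -0.45) and with the right lens of KO animal 1 only (0.0325, median -0.25), and pigmented epithelium without KO animal 1 (0.00691, median 0.63). Without WT animal 2, muscle (6.05e-06, median 0.79) and the ciliary epithelium (0.0166, median 0.37) passed, and without WT animal 6 muscle passed the other way (0.0451, median -0.40). Gnat1, the rod transducin, was at 13.89 in KO and 13.94 in WT, at percentile 99.0 of all genes by level. The captured samples thus held retinal transcripts in both groups.

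**Figure D3:**
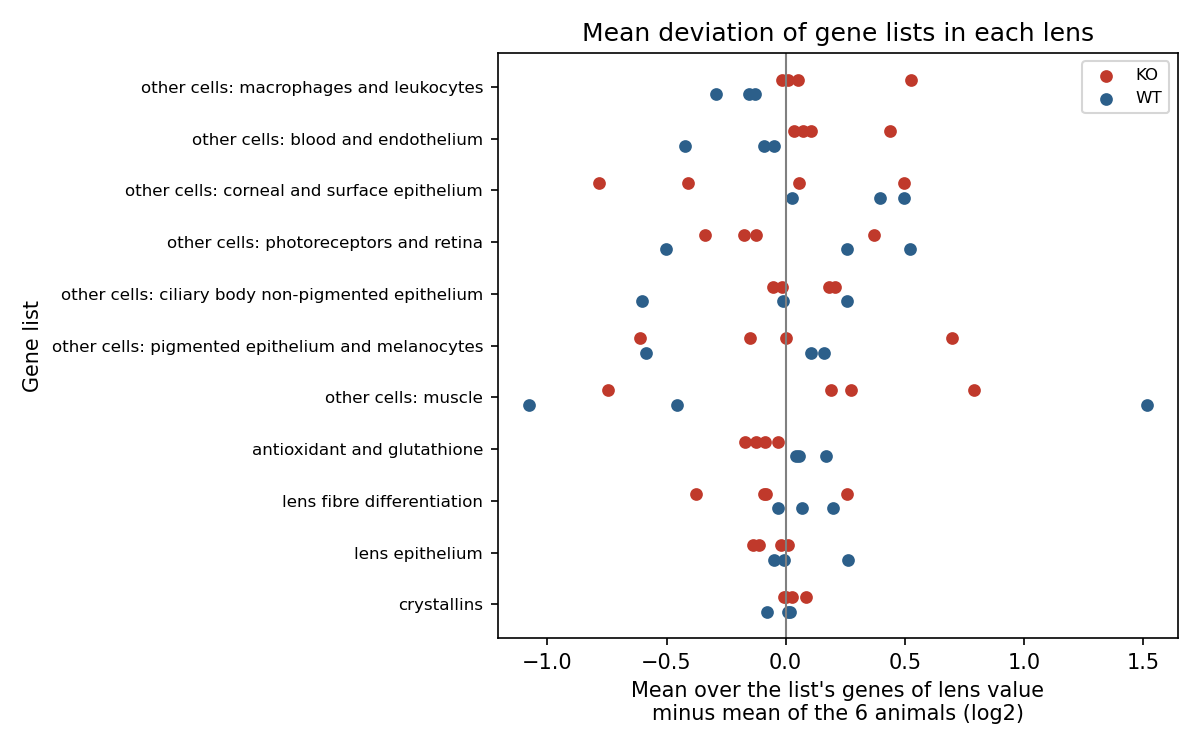
Mean over the genes of 11 lists of the log2 value in each lens minus the average of the 6 animals (horizontal axis), KO lenses in red and WT lenses in blue. KO lens 4L stands at 0.53 for macrophages and leukocytes, and muscle genes run from -1.08 in 6L to 1.51 in 2L.

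The other 13 lists covered transport, junctions, signalling, stress and metabolism, and none passed in camera (adjusted p 0.340 to 0.999). Medians above 0 were 0.10 for ion, water and solute transport, 0.09 for cholesterol synthesis, 0.03 for immediate early genes, and 0.01 for both FGF signalling and cytosolic heat shock, and with median centring the last 4 were -0.0053, -0.019, -0.080 and -0.070. Medians below 0 were -0.15 for the cell cycle, -0.09 for glycolysis and hypoxia, -0.07 for endoplasmic reticulum stress, -0.06 for ribosomal proteins, -0.03 for both the respiratory chain and Wnt and BMP signalling, and -0.01 for interferon response and antigen presentation, and with the signals as deposited the last 2 were 0.031 and 0.0023. The cell-cell junction list stood at -4.01e-04, or 0.0094 with the signals as deposited. Slc2a3, a neuronal-type glucose transporter, was at 9.54 ± 0.35 in KO and 7.98 ± 0.65 in WT, and Ifitm3, an interferon-induced membrane protein, at 11.94 ± 0.41 and 10.66 ± 0.53 (SD, n = 3). Both passed adjusted over their list alone and not over all probe sets (limma). Egr1, Nr4a1 and Klf4, immediate early transcription factors, had log2 differences of 0.67, 0.84 and 0.58 with unadjusted p under 0.05 in limma. Median, mean and test differed in sign for the interferon, integrin and cell-cell junction lists. Over all 29 lists, 4 passed with the preset correlation of 0.01 and 0 with an estimated correlation, where 2 had an unadjusted p under 0.05.

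Genes beside Sparc on its chromosome were compared with other genes, since flanking chromosome of the strain in which a knockout was made can differ between littermates. Of 148 measured protein-coding genes among the 100 on each side of Sparc, 8 (5.41%) had an unadjusted p under 0.05, against 658 of 16319 others (4.03%). The odds ratio was 1.36 (95% interval 0.573 to 2.77, Fisher's exact test, two-sided, p = 0.396). It was 0.954 without KO animal 4, 0.993 without WT animal 2 and 0.769 with the filter on low values, and 2.41 at the stricter unadjusted p of 0.01.

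Both eyes of KO animal 1 differed from each other about as much as eyes of different mice. The SD of the log2 difference over probe sets was 0.699 between 1L and 1R, 0.649 to 0.798 over 8 pairs of lenses from different animals of one group, and 0.639 to 0.763 over 12 pairs from different groups. Only 1 pair of eyes from one animal was measured, so this value has no error. The first principal component held 23.8% of the variance and had KO lenses on both sides.

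The sex labels were checked with Xist, the RNA of the inactive X chromosome, and with Y-linked genes. Xist signal was 119 in lens 7L, labelled male, and 14341 to 24815 in the 6 lenses labelled female. Eif2s3y was at 1198 in 7L and 0.645 to 16.05 in the others, and Uty at 447 and 7.30 to 21.8. Of 3 Kdm5d probe sets, 1 was at 230 in 7L and 1.15 to 29.2 in the others, and the other two did not separate 7L (54.0 against 2.59 to 62.7, and 2.35 against 1.95 to 21.0).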

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

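The tests of explanations for the leukocyte list were chosen after its call had been seen. Each of 148 values was checked for a lens far from the other KO lenses, by the gap to the nearest lens over the range of the 4, and 9 (6.08%) stood out, where chance gives about 1 in 20. Groups of 3, such as WT, were not checked.

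Xist in lens 7L had a gap of 0.916 of the range, Eif2s3y one of 0.882 and Uty one of 0.877, and 7L is the lens labelled male. Pcdh9 was lower in 4L (8.81, others 9.07 to 9.09; gap 0.929). Uqcrc1, a subunit of respiratory complex III, was lower in 1R (11.77, others 12.45 to 12.60; gap 0.8291). Dhcr7, of cholesterol synthesis, was lower in 7L (9.72, others 10.89 to 11.06; gap 0.869). Krt5 was lower in 7L (6.74, others 9.83 to 10.41; gap 0.843). The mean of the TGF-beta list was lower in 1L (-0.08, others 0.06 to 0.07; gap 0.927).

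The mean of the macrophage and leukocyte list was 0.53 in 4L and -0.02 to 0.05 in the other KO lenses (gap 0.874), and this list had the smallest camera p of the 29 lists fixed beforehand. The sex of KO animal 7 is argued against as its source, since the list median was 0.451 without that animal. Without the WT lens 2L the list kept its call (median 0.394, camera adjusted p = 0.00354). RNA quality or low array signal of that lens, the one with the lowest 3' to 5' ratios, stays open only as a part of the difference. Leukocytes taken along in the capture, or a greater number of macrophages in KO eyes, an untested biological difference, stay open: the 6 transcripts C1qa, C1qb, C1qc, Lyz2, Tyrobp and Ctss had a median log2 difference of 0.860, but all are members of the list and so give no independent support. Of these transcripts Ctss was at 10.04 in KO and 9.20 in WT, and Lyz2 at 8.64 and 8.11.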

How the results depend on the processing

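The block for the animal and the signals as deposited were chosen after the data had been seen. Sparc stayed past the threshold in limma under every alternative run, with a log2 difference of -10.73 to -8.82 at its brightest probe set, and so did the next brightest, with -10.26 to -8.20. The number of probe sets past the threshold was 3, or 2 without the intensity trend and without KO animal 1, KO animal 4, KO animal 7, WT animal 5 or WT animal 6, where the unnamed probe set was lost (adjusted p 0.0879 to 0.225; elsewhere 0.00381 to 0.0490), its log2 difference being 2.86 to 3.40 throughout. Over named genes, 1829 values kept direction and side of the threshold, 6 lost the call, all of the unnamed probe set, and 3 turned. Apart from Sparc, only the unnamed probe set had a call to lose. The genes named as higher or lower were chosen for no overlap between lenses, so their direction could hardly turn. The count is therefore no measure of robustness. At an unadjusted p under 0.05 there were 1828 probe sets, 3150 with array weights and 771 with the filter, which left 22518 to test. The planned estimate of the correlation between lenses of one animal was not run, since a single pair gives none, and quantile normalization was already the chosen setting. No paired analysis was possible because the groups share no replicate numbers. The cause of the changes given here was not tested, and with so few arrays weak signals near the bacterial controls limit what can be seen.

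The number of lists past the threshold in camera was 4, 2 with the filter on low values, 2 with array weights, 0 with an estimated correlation, and 1 to 6 with an animal left out (1 without KO animal 4 or KO animal 7). Over list medians, 425 values kept direction and side, 22 lost the call, 8 gained it and 67 turned, 1 of these past the threshold (muscle without WT animal 6, median -0.40, camera adjusted p = 0.0451). With 7 lenses the medians that turned were -8.93e-04 for integrins and 0.081 for interferon. With the left lens of KO animal 1 they were -0.037 for integrins, -0.067 for heat shock, 0.056 for interferon and 0.015 for the respiratory chain, and with the right lens 0.022 for junctions, 0.054 for Wnt and BMP and -0.095 for muscle. Median centring gave -0.038 for integrins, -0.0045 for TGF-beta, -0.070 for heat shock, -0.080 for FGF, -0.019 for immediate early genes, -0.0053 for cholesterol and -0.031 for muscle. The signals as deposited gave 0.0094 for junctions, 0.031 for Wnt and BMP and 0.0023 for interferon. Array weights gave -0.030 for integrins, -0.020 for TGF-beta, -0.038 for heat shock, -7.56e-04 for FGF and 0.10 for interferon. The filter gave 0.026 for junctions, -0.011 for FGF and -0.026 for the ciliary list. A pseudocount of 64 gave 6.35e-05 for junctions and -0.0084 for muscle, and the mean of all probe sets -0.0017 for ion transport, -0.019 for heat shock, -0.029 for cholesterol and -0.039 for muscle.

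With each animal left out in turn, medians ran from -0.25 to -0.058 for the fibre list, -0.17 to -0.027 for the lens epithelium, -0.26 to 0.011 for stromal matrix, -0.14 to 0.032 for the SPARC family, -0.031 to 0.045 for integrins, -0.052 to 0.15 for TGF-beta, -0.051 to 0.030 for junctions, -0.095 to 0.012 for endoplasmic reticulum stress, -0.017 to 0.096 for heat shock, -0.058 to 0.16 for FGF, -0.063 to 0.077 for Wnt and BMP, -0.099 to 0.19 for immediate early genes, -0.089 to 0.15 for interferon, -0.15 to 0.069 for the respiratory chain and -0.0011 to 0.22 for cholesterol. Among marker lists they ran from -0.010 to 0.63 for pigmented epithelium, -0.45 to 0.051 for photoreceptors, -0.40 to 0.79 for muscle and -0.012 to 0.37 for the ciliary epithelium. Crygn ran from -0.47 to 0.031, Des from -0.073 to 1.44 and Ckm from -1.21 to 0.30. The odds ratio beside Sparc was 0.769 with the filter, 0.954 to 1.46 with an animal left out, and 1.12 to 2.41 with other windows and the stricter p. The SD between the lenses of KO animal 1 was 1.10 with a pseudocount of 1 and 0.486 with one of 64, and Xist in 7L lay at -6.66 against the females with a pseudocount of 64.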

Other observations

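The acute-phase tests, including the one without KO animal 4, were chosen after the genes of smallest p had been seen. Several transcripts of neighbouring tissues were abundant in the captured samples. In the top 10% of all genes by level lay 14 of 20 photoreceptor, 7 of 17 muscle, 5 of 15 corneal and 3 of 14 pigmented epithelium genes. It was 2 of 13 for the ciliary epithelium and 0 for the blood and leukocyte lists. By percentile of level, Pdc stood at 99.0, Sag at 98.6, Dct at 97.4, Myh1 at 95.2 and Krt12 at 94.1. A difference between KO and WT samples, also in the named genes, can therefore not be placed in the lens epithelium alone. The log2 levels were as follows. Among photoreceptor genes, Pdc was at 13.90 in KO and 13.97 in WT, and Sag at 13.62 in both. Dct, of melanin synthesis, was at 13.46 ± 0.77 and 12.68 ± 1.07, and Krt12, the keratin of the corneal epithelium, at 11.45 ± 2.07 and 12.84 ± 1.07 (SD, n = 3). Of the skeletal muscle genes, Tnnc2 was at 12.60 and 12.41, Myh1 at 12.61 and 12.17, and Acta1 at 12.32 and 12.41. The mean over the muscle list ran from -1.08 in WT lens 6L to 1.51 in WT lens 2L, the widest range of the 7 marker lists.

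Of 14 pigmented epithelium genes, 9 were higher and 5 lower in KO, none past the adjustment in limma. Mlana was at 10.90 ± 0.60 in KO and 9.98 ± 0.59 in WT, Tyr at 10.05 and 8.99, and Rlbp1, the retinaldehyde-binding protein, at 9.98 ± 0.05 and 9.51 ± 0.08. Rpe65, the isomerase of the retinal pigment epithelium, was at 7.57 ± 0.09 in KO and 8.70 ± 0.68 in WT, and Rgr, an opsin of the same tissue, at 8.74 ± 0.38 and 9.57 ± 0.62 (SD, n = 3). The list median was -0.01 without KO animal 7.

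Socs3, Bcl3, Serping1 and Tnfrsf1a, which act in cytokine, NF-kB, complement and tumour necrosis factor signalling, were all among the 12 named genes of higher value. The hypothesis that the KO tissue has an acute-phase response was set against a list of 30 other genes of that response, 29 of them measured and 2 held by other lists. Of these, 20 were higher in KO with a median log2 difference of 0.20, and camera gave an unadjusted p of 3.70e-05 (0.0121 with an estimated correlation). All 5 with an unadjusted p under 0.05 in limma were higher, 3 of them past the adjustment over the list alone: Gfap, an intermediate filament protein (1.47), Osmr, the oncostatin M receptor (1.04), Timp1 (1.41), Stat3 (0.54) and Serpina3n (1.27). None passed over all probe sets.

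RNA quality or low array signal of the WT lens 2L, the sex of KO animal 7 and leukocytes in the captured tissue all stay open. The median log2 difference of the 4 genes was 1.78 without WT animal 2, 1.91 without KO animal 7 and 1.79 without KO animal 4, but genes chosen for no overlap between KO and WT lenses stay apart whichever lens is left out. The acute-phase list, which was not chosen that way, had a camera p of 0.00187, 7.02e-04 and 0.00216 there, while the leukocyte list median was still 0.24 without KO animal 4. Of the 10 splits of the 6 animals into 3 and 3, 1, the real one, gave a camera p of the acute-phase list as small (3.70e-05, smallest other 0.00595), 1 other had a larger list median (0.22 against 0.20), and 10 splits are too few for a share under 0.05. An acute-phase response, in the lens epithelium or in other cells captured with it, may account for these values, and this remains a hypothesis found and tested on the same arrays.

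The same 10 splits were run for the main counts. 1 split gave as many probe sets past the threshold, the real one with 3, and the highest of the others had 0, but 2 of the 3 belong to Sparc itself. At an unadjusted p under 0.05, 5 other splits gave more than the real one with 1828, up to 4383 for animals 1, 2 and 7 against 4, 5 and 6. As many gene lists were past the threshold in 4 splits, where the real one gave 4 and the highest other 6. In neither case can the share fall under 0.05 with so few animals. Flanking chromosome from another strain cannot be told apart from chance beside Sparc, with an odds ratio of 1.36 whose interval reaches 2.77 and alternatives of 0.769 to 2.41.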
